A study of Mus musculus with 8 samples.

How the data were processed

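Bulk RNA-seq libraries of 3 sorted fetal liver populations were analysed: CLP (3 libraries), ILCP (3) and ILC1/3P (2). Groups and replicate numbers came from the sample titles. Per the labels' protocols, sorted cells were lysed, cDNA was made in the lysate with a SMARTer Ultra Low kit and amplified by PCR, and libraries were sequenced on a NovaSeq6000. The deposited table gives whole-number counts per gene and, in separate columns, FPKM computed by the authors. The build was mm10 per the submitters' processing notes. The aligner, the counting program, the annotation release and the use of strand are not given in the sources used here. No molecular identifiers are described, so intervals and floors cover counting error only.

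The table held 34745 genes with identifiers, symbols and coordinates, 67 of them with a symbol used more than once, and 0 columns were left unmapped. Coordinates are those of the table. For exon overlaps, transcript length and GC content, identifiers were matched to GENCODE M21: 34267 were found, 27699 of them at an identical locus. Because strand use is not given, genes whose exons overlap another gene are uncertain. Among the genes named these are Adh1, Agpat9, Atp5j, Bcl11a, Bcl2, Ccr9, Cd160, Cd34, Cox6a2, Gata3, Gbp2, Gp1bb, H2-DMa, Ifng, Il2rg, Itga4, Klrb1b, Klrb1c, Maf, Mpo, Myb, Notch1, Rag1, Rora, Rtp4, Slamf7, Stab2, Themis, Tox, Usp18 and Xcl1, and Scamp4 by the table's own coordinates. Near-identical family members (Klrc1 and Klrc2, the Klra genes, Il22 and Iltifb, and the Tcrg constant genes) are uncertain for the same reason, as are genes with many processed copies. Gapdh had only 7.21 ± 1.11 CPM in CLP, 7.11 ± 1.46 CPM in ILCP and 6.53 ± 4.81 CPM in ILC1/3P, which points to loss of reads shared with such copies, and ribosomal protein and oxidative phosphorylation counts may carry the same loss.

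The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 13436, libraries were scaled by TMM, and a quasi-likelihood model with robust dispersion was fitted to all 8 libraries with 1 mean per group. Adjusted p-values are Benjamini-Hochberg values from its two-sided test, and genes with an adjusted p under 0.05 were called. Standard errors of log2 fold changes were derived from the F statistic. The biological coefficient of variation was 0.679, with 5 residual and 6.49 prior degrees of freedom. CPM values are counts scaled to the TMM-adjusted library size, given as mean ± SD over the libraries of a group. Where a group had no counts, the fold is a bound: the counts pooled over the other group, per pooled TMM-adjusted size, against a floor of 3 counts pooled over that group. Pooling weights larger libraries more, so a bound can lie above or below the printed mean over that floor. With 1 to 3 counts the ratio of pooled counts is given with its 95% counting interval. List medians are also given with absent genes at that bound where this changed them.

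Gene lists were written before the data were examined, together with the design, the naming rule and most of the alternatives. They cover sort markers, innate lymphoid progenitor regulators, multipotent progenitor, B-lineage, NK and ILC1, ILC2, ILC3 and lymphoid tissue inducer, T lineage, Notch, common gamma chain signalling, residency, egress, cell cycle, glycolysis, oxidative phosphorylation, ribosomal protein, interferon response, MHC class II and immediate early genes. Some genes belong to several lists. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and, as an alternative, with an estimated correlation and with fry, and p-values were adjusted over the 19 lists of a comparison. Further lists of erythroid, myeloid, mast cell and basophil, megakaryocyte, dendritic, hepatocyte, and endothelial and stromal genes describe RNA of other cell types. Not matched in the table were Cd244a, Hbb-b1, Hbb-b2 and Ahsp. Genes were named by a fixed rule. Per comparison and direction it takes the 6 called genes with the largest fold among those with at least 20 CPM in the higher group and no overlap between groups, leaving out predicted genes, pseudogenes and receptor segments. It adds every sort marker, up to 4 members of each list with the smallest p, and the 2 most abundant members of each other-cell list. Not every gene that the rule takes is reported here. Genes named outside it are said to be chosen after their values were seen.

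The programs were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. At an 8-fold change edgeR recovered 52.9% of them for ILCP against CLP (12741 genes tested), 44.7% for ILC1/3P against CLP (12729) and 49.2% for ILC1/3P against ILCP (12695), and 5.61%, 3.41% and 3.16% of its calls were false. At 4-fold it recovered 29.2%, 20.8% and 30.4% (12722, 12691 and 12695 genes tested), at 16-fold 68.6%, 61.1% and 56.5% (12727, 12689 and 12705), and at 2-fold 0% in each (12678, 12744 and 12669), so most changes of that size would be missed. At 8-fold DESeq2 recovered 69.0%, 62.9% and 66.9%, but 30.6%, 29.9% and 27.8% of its calls were false (11915, 11912 and 11645 genes tested). With limma-trend 14.8%, 7.14% and 4.12% of calls were false. A length trend put into simulated counts gave correlations with transcript length of -0.343, -0.315 and -0.306, and removing it left 0.00175, -0.005 and -0.00135 (12703, 12676 and 12672 genes).

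The alternatives set in advance were RLE size factors, library size without further scaling, DESeq2 1.42.0, limma-voom, no filter and a stricter filter on low counts, fits with only the groups compared, a fit with the replicate number as a block, a minimum change of 2-fold, other list tests, and leaving out each library in turn. Chosen after the data were seen were limma-trend on log2(FPKM + 1) of the deposited FPKM, thinning of every library to 4991939 counts, and removal of smooth trends with transcript length and GC content. Transcript length correlated with the fold changes at -0.063, -0.098 and -0.078 (Spearman, across 13390 genes, in the order ILCP against CLP, ILC1/3P against CLP, ILC1/3P against ILCP) and GC content at -0.016, -0.01 and -0.00418. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.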

Results

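Bulk RNA was sequenced from 3 lymphoid progenitor populations sorted from the fetal liver of wild-type B6 mice. The labels call them CLP (n = 3), ILCP (n = 3) and ILC1/3P (n = 2). The CLP gate took Flt3+ cells, the ILCP gate Flt3– α4β7+ PD-1+ CD94– cells and the ILC1/3P gate Flt3– α4β7+ PD-1– CD94+ cells, and all gates shared a lineage-negative, CD45+ CD127+ CD25– profile. Total counts ran from 4991939 to 7167619 per CLP library, from 6043940 to 6905448 per ILCP library and from 6310739 to 8082476 per ILC1/3P library. The labels give 1 batch date for all 8 libraries, so no batch comparison was possible. They also carry an age of 6 to 8 weeks, which the fetal tissue leaves unexplained. No label says that the libraries came from separate animals or litters, so p-values measure only the spread between these samples, which may be technical. Intervals and floors cover counting error only, and bounds (at least) and ratios come from counts pooled over a group, not from the means beside them.

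The 3 populations lay apart in the plot of principal components, and each library lay closest to its own group. Correlations of log2 CPM across genes, which are not independent replicates, were 0.890 to 0.897 among CLP libraries, 0.862 to 0.881 among ILCP libraries and 0.857 between the ILC1/3P libraries. Between groups they ran from 0.671 to 0.800. ILC1/3P libraries had fewer genes with a count (12230 to 12705) than ILCP (13019 to 13703) or CLP libraries (13454 to 14171). Their 50 most abundant genes took 24.8% to 29.2% of counts, against 12.9% to 16.03% in CLP and 15.1% to 18.0% in ILCP. Mitochondrial genes took 4.91% to 5.39% of counts in ILC1/3P, 2.70% to 4.53% in CLP and 2.71% to 4.13% in ILCP.

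**Figure D1:**
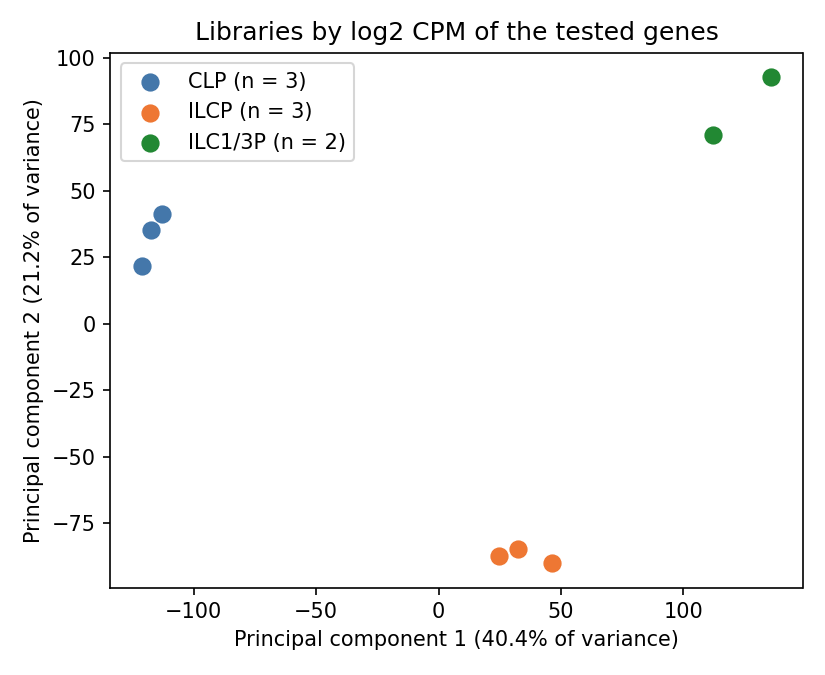
Principal components of log2 CPM of the tested genes, 1 point per library, coloured by group; component 1 (x axis) held 40.4% and component 2 (y axis) 21.2% of the variance. CLP, ILCP and ILC1/3P libraries occupy separate regions.

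Flt3, Pdcd1 and Klrd1 were each highest in the population gated for their product. Flt3 (ENSMUSG00000042817, chromosome 5, 147330741 to 147400489 on mm10) averaged 459 ± 96.1 CPM in CLP (SD, n = 3) and 0.427 ± 0.739 CPM in ILCP (SD, n = 3), and had no counts in ILC1/3P (n = 2). Pdcd1, which encodes PD-1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), had no counts in CLP and averaged 77.7 ± 31.4 CPM in ILCP and 13.8 ± 5.16 CPM in ILC1/3P. Klrd1, which encodes CD94 (ENSMUSG00000030165, chromosome 6, 129591782 to 129598775), averaged 1407 ± 315 CPM in ILC1/3P, 44.7 ± 26.2 CPM in ILCP and 52.2 ± 12.4 CPM in CLP. Itgb7 was higher in ILCP and ILC1/3P than in CLP (4.16 ± 0.77 and 3.69 ± 0.79, log2 ± SE, adjusted p = 0.00576 and 0.00545). Il7r, Itga4 and Ptprc did not pass the threshold between ILCP and CLP. Il7r (-1.02 ± 0.24, adjusted p = 0.00968) and Itga4 (-1.46 ± 0.29, adjusted p = 0.0036) were lower in ILC1/3P than in CLP. Il2ra had no counts in CLP, 7.57 ± 1.54 CPM in ILCP and 2.30 ± 2.09 CPM in ILC1/3P. Its calls against CLP were lost for ILCP without any 1 of the 6 CLP and ILCP libraries (highest adjusted p = 0.0645) and for ILC1/3P without CLP replicate 1 or ILC1/3P replicate 2 (highest adjusted p = 0.0825). The Pdcd1 difference between ILC1/3P and ILCP (-2.49 ± 0.57, adjusted p = 0.0165) was also lost without ILCP replicate 1 or 3 or ILC1/3P replicate 1 (highest adjusted p = 0.0815), and the Il7r call against CLP was lost without ILC1/3P replicate 2 (adjusted p = 0.0528). Of the 8 sort markers, 3 were higher and 1 lower in ILCP than in CLP, 4 and 3 in ILC1/3P than in CLP, and 1 and 3 in ILC1/3P than in ILCP, with the same counts adjusted over the list alone. As a list they were not called (camera adjusted p = 0.471, 0.58 and 0.581). Flt3, PD-1, CD94 and α4β7 were gated on, so the differences in Flt3, Pdcd1, Klrd1 and Itgb7 are not independent findings.

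**Figure D2:**
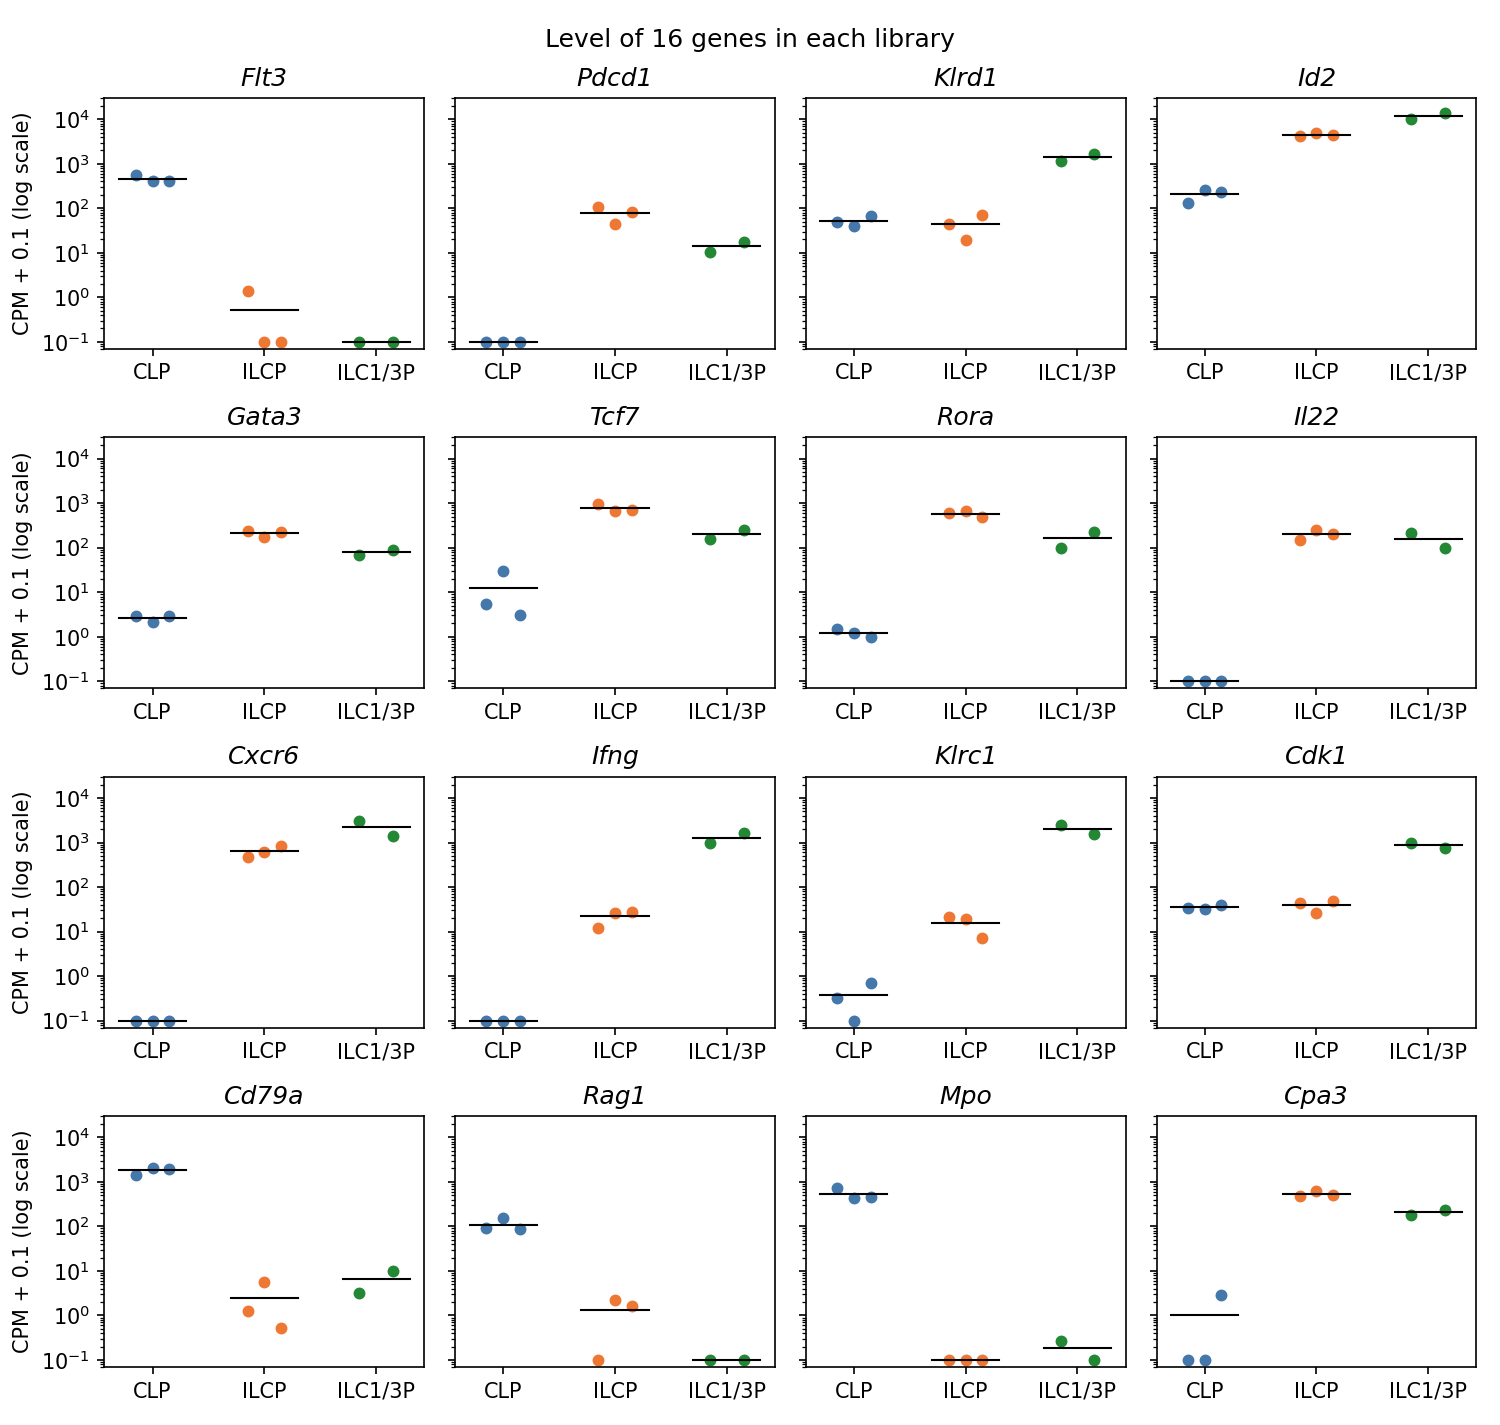
CPM + 0.1 (log axis) of 16 genes in each library, points coloured by group, with a bar at each group mean. Id2 averaged 208 ± 68.7 CPM in CLP, 4537 ± 414 CPM in ILCP and 12045 ± 2925 CPM in ILC1/3P (SD).

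The comparison of ILCP with CLP asked what sets the PD-1+ gate of innate lymphoid progenitors apart from lymphoid progenitors that still carry Flt3. Gata3, Rora, Id2 and Bcl11b, which encode transcription factors of the innate lymphoid program, were higher in ILCP. Gata3 (ENSMUSG00000015619, chromosome 2, 9857078 to 9890034) averaged 215 ± 34.1 CPM in ILCP and 2.56 ± 0.463 CPM in CLP (SD, n = 3 each), a log2 fold change of 6.37 ± 0.33 (SE, edgeR adjusted p = 1.07e-06). Rora rose by 8.99 ± 0.44 on the log2 scale (adjusted p = 7.08e-07) and Id2 (ENSMUSG00000020644, chromosome 12, 25093801 to 25096092) by 4.44 ± 0.31 (adjusted p = 6.04e-06). Bcl11b had no counts in CLP and was at least 581-fold higher in ILCP (83.0 ± 10.3 CPM). Among the progenitor regulators, 10 genes were higher and 0 lower of 17 tested (10 and 1 adjusted over the list alone), with a list median of 3.61 (camera adjusted p = 2.91e-24, and 0.00324 with an estimated correlation).

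ILCP also carried genes of each helper-like branch and of the T lineage. Il22, the cytokine of ILC3, which shares sequence with the near-identical Iltifb, had no counts in CLP and averaged 203 ± 52.0 CPM in ILCP, at least 1425-fold higher. Arg1, an ILC2 gene, rose by 9.72 ± 0.41 (adjusted p = 2.66e-07) to 1524 ± 229 CPM. Cxcr6 (ENSMUSG00000048521, chromosome 9, 123806477 to 123811754) was at least 4454-fold higher, Txk at least 1888-fold, Ccr8 at least 1700.2-fold, Themis at least 1172-fold and Klrb1b at least 1015-fold, each against a CLP group without counts. Of the ILC3 and lymphoid tissue inducer genes, 10 were higher and 0 lower of 21 (14 and 1 adjusted over the list alone; median 3.62, camera adjusted p = 4.53e-17), including Lta (2.84 ± 0.28) and Ltb (2.30 ± 0.22). Of the ILC2 genes, 11 were higher and 1 lower of 23 (15 and 1 adjusted over the list alone; median 7.25, or 4.71 with genes absent from a group at their bound, camera adjusted p = 1.04e-31). Of the NK and ILC1 genes, 18 were higher and 3 lower of 34 (24 and 3 adjusted over the list alone; median 3.68, or 3.35 with bounds, camera adjusted p = 5.36e-21), including Nkg7 (3.71 ± 0.34) and Cd160 (7.15 ± 0.67). Of the T lineage genes, 16 were higher and 0 lower of 23 (20 and 2 adjusted over the list alone; median 6.47, or 5.16 with bounds, camera adjusted p = 1.17e-35). Tcrg-C4 (ENSMUSG00000076757, chromosome 13, 19344558 to 19352756) reached 1663 ± 323 CPM from no counts, and Trbc1 rose by 6.55 ± 0.27 (adjusted p = 2.66e-07). All 4 lists were also called with an estimated correlation (adjusted p = 0.000974, 0.000382, 0.00287 and 0.000382 in the order given).

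Multipotent and B-lineage genes were lower in ILCP than in CLP as lists, and 3 of 12 myeloid and 6 of 10 dendritic genes tested were lower as single genes, with 0 and 1 higher. Mpo (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413), the granule enzyme of early myeloid cells, averaged 534 ± 154 CPM in CLP and had no counts in ILCP, at least 3974-fold lower. Cd79a averaged 1829 ± 369 CPM in CLP and 2.36 ± 2.76 CPM in ILCP, a log2 fold change of -9.58 ± 0.78 (adjusted p = 1.77e-05). Cd34 changed by -5.43 ± 0.34 (adjusted p = 5.81e-06), Bcl11a by -5.14 ± 0.54 (adjusted p = 0.000118) and Myc by -2.72 ± 0.27 (adjusted p = 6.84e-05). With no counts in ILCP, Tifab was at least 544-fold lower, Pou2af1 at least 531-fold, Siglech at least 477-fold, Cd33 at least 471-fold and Agpat9 at least 449-fold. Blnk had 1 count in ILCP, a CLP to ILCP ratio of 2943 (95% interval 528 to 116268). Of the B-lineage genes, 0 were higher and 19 lower of 23 (0 and 21 adjusted over the list alone; median -6.24, camera adjusted p = 2.66e-42). Of the multipotent progenitor genes, 0 were higher and 13 lower of 22 (1 and 18 adjusted over the list alone; median -4.14, camera adjusted p = 4.95e-27). Both were called with an estimated correlation (adjusted p = 0.000382 and 0.000974). Of the 24 interferon response genes, 1 was higher and 7 lower (2 and 10 adjusted over the list alone). With library size as the only scaling 0 were higher and 7 lower. The list was lower, with a median of -2.18 (camera adjusted p = 9.11e-06, and 0.00877 with an estimated correlation). Usp18 changed by -3.09 ± 0.54 (adjusted p = 0.0044) and Rtp4 by -2.24 ± 0.29 (adjusted p = 0.000548).

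Other programs differed less between ILCP and CLP. Hey1 rose by 5.08 ± 0.70 (adjusted p = 0.000775) while Notch1 changed by -4.51 ± 0.48 (adjusted p = 0.000131), and these were the called genes of the 10 Notch genes (1 and 1 adjusted over the list alone, camera adjusted p = 0.224). Bcl2 rose by 2.75 ± 0.31 (adjusted p = 0.000187) and Il2rg by 1.83 ± 0.26 (adjusted p = 0.00103); of the 21 common gamma chain genes 4 were higher and 0 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.0621). Ccr2 rose by 5.19 ± 0.49 (adjusted p = 5.98e-05), and of the 14 egress genes 2 were higher and 2 lower, or 1 and 2 with library size only (4 and 3 adjusted over the list alone, camera adjusted p = 0.471). Cd69 changed by -2.14 ± 0.28 (adjusted p = 0.000481), and of the 14 residency genes 2 were higher and 2 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.251). Glycolysis genes were higher as a list (5 higher and 1 lower of 22, 7 and 3 adjusted over the list alone; median 0.74, camera adjusted p = 0.00802), but not with an estimated correlation (adjusted p = 0.371) and not without ILCP replicate 1 (adjusted p = 0.0527). The ribosomal protein list had a median of -0.33 (camera adjusted p = 0.00211, adjusted p = 0.673 with an estimated correlation and 0.0575 without CLP replicate 3), with 0 of 83 genes called by edgeR in either direction, also adjusted over the list alone (16 genes at an unadjusted p under 0.05). Cell cycle genes were not called as a list (0 higher and 2 lower of 37, 1 and 5 adjusted over the list alone, camera adjusted p = 0.23), and the calls of Mcm2 (-1.15 ± 0.29) and Mcm6 (-1.02 ± 0.27) were lost with library size only and when any single library of either group was left out (highest adjusted p = 0.141 and 0.161). Oxidative phosphorylation genes (2 and 2 of 83, 1 and 1 adjusted over the list alone, camera adjusted p = 0.189), MHC class II genes (0 and 2 of 10, 2 and 4 adjusted over the list alone, camera adjusted p = 0.23) and immediate early genes (2 and 1 of 22, 5 and 2 adjusted over the list alone, camera adjusted p = 0.792) were not called. Oxidative phosphorylation was called without CLP replicate 3, without ILCP replicate 1 and without either ILC1/3P library (adjusted p = 0.00327, 0.028, 0.0335 and 0.034). The MHC class II list had a median of 1.06 while camera placed it lower, and its called genes were H2-DMa (-2.90 ± 0.27) and H2-Ob (-2.13 ± 0.37).

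In all, 526 genes were higher and 386 lower in ILCP than in CLP of 13436 tested (6.79%). Among tested genes 3786 had no overlap between the groups' libraries, where chance gives 10%. The median of all genes was 0.007. Leaving out ILCP replicate 3 reduced the higher count to 347 and the lower count to 250, and leaving out CLP replicate 2 or 3 reduced the lower count to 215 or 216.

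The comparison of ILC1/3P with CLP asked the same of the CD94+ gate. Of the 19 gene lists, the NK and ILC1 genes had the highest median. Ifng (ENSMUSG00000055170, chromosome 10, 118441047 to 118445892) averaged 1288 ± 474 CPM in ILC1/3P (SD, n = 2) and had no counts in CLP (n = 3), at least 8594-fold higher. Cxcr6 was at least 16568-fold higher, Klrb1b at least 5607-fold, Tmem37 at least 3241-fold, Ncr1 at least 2502-fold and Ccr8 at least 2177-fold. Klrc1 (ENSMUSG00000030167, chromosome 6, 129666015 to 129678973) rose by 12.68 ± 0.71 (SE, adjusted p = 1.46e-06), although reads shared with its close paralog Klrc2 leave the split between them uncertain. Of the NK and ILC1 genes, 28 were higher and 0 lower of 34 (30 and 1 adjusted over the list alone), with a median of 7.55, or 5.78 with bounds (camera adjusted p = 7.05e-40, and 0.00241 with an estimated correlation). Relative to the median of all genes, which stood at -0.25 here, the list median was 7.80.

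The regulators, ILC2, ILC3 and T lineage lists were higher than in CLP here too. Id2 rose by 5.85 ± 0.34 (adjusted p = 1.63e-06), Rora by 7.14 ± 0.43 (adjusted p = 1.69e-06), Gata3 by 4.94 ± 0.33 (adjusted p = 3.19e-06) and Maf by 3.77 ± 0.38 (adjusted p = 6.05e-05). Of the regulators, 9 were higher and 0 lower (11 and 1 adjusted over the list alone; median 1.59, 1.84 relative to all genes, camera adjusted p = 8.71e-10). Of the ILC2 genes, 11 were higher and 0 lower (13 and 1 adjusted over the list alone; median 3.90, or 3.03 with bounds, camera adjusted p = 6.74e-13). Of the ILC3 genes, 9 were higher and 1 lower (11 and 2 adjusted over the list alone; median 3.23, camera adjusted p = 1.29e-07). Il22 averaged 154 ± 80.6 CPM, at least 1148-fold above CLP. Of the T lineage genes, 15 were higher and 0 lower (16 and 1 adjusted over the list alone; median 4.59, or 3.67 with bounds, camera adjusted p = 3.92e-16), and Tcrg-C4 was at least 6734-fold higher. With library size only the regulators split 7 and 1 and the ILC3 genes 9 and 3. The list calls held with an estimated correlation (adjusted p = 0.0173, 0.00241, 0.00604 and 0.00241 in the order given).

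Multipotent and B-lineage genes of CLP were lower in ILC1/3P as well. Flt3 was at least 1629-fold lower, Cd34 (ENSMUSG00000016494, chromosome 1, 194938819 to 194961279) at least 1126-fold, Blnk at least 473-fold, Igll1 at least 391-fold and Rag1 at least 362-fold. Mpo kept 1 count in ILC1/3P, a CLP to ILC1/3P ratio of 5751 (95% interval 1032 to 227189.8). Of the B-lineage genes, 0 were higher and 20 lower (0 and 22 adjusted over the list alone; median -6.85, or -5.69 with bounds, camera adjusted p = 1.22e-18, and 0.00241 with an estimated correlation). Of the multipotent genes, 0 were higher and 18 lower (0 and 21 adjusted over the list alone; median -4.45, or -4.32 with bounds, camera adjusted p = 1.98e-17, and 0.005 with an estimated correlation).

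Genes of division, respiration and translation were higher in ILC1/3P than in CLP. Cdk1 rose by 4.63 ± 0.31 (adjusted p = 3.32e-06) from 34.9 ± 4.47 to 865 ± 137 CPM, Birc5 by 3.76 ± 0.24 (adjusted p = 2.51e-06), Mki67 by 2.99 ± 0.31 (adjusted p = 7.52e-05) and Tyms by 2.97 ± 0.29 (adjusted p = 4.76e-05). Of the 37 cell cycle genes, 12 were higher and 1 lower, or 8 and 2 with library size only (13 and 1 adjusted over the list alone; median 0.99, 1.24 relative to all genes, camera adjusted p = 4.1e-07), but the list was not called with an estimated correlation (adjusted p = 0.198). Atp5j rose by 2.91 ± 0.33 (adjusted p = 0.000113) and Uqcr10 by 2.83 ± 0.32 (adjusted p = 0.000118). Of the 83 oxidative phosphorylation genes, 53 were higher and 8 lower, or 44 and 13 with library size as the only scaling (59 and 10 adjusted over the list alone; median 1.55, 1.80 relative to all genes, camera adjusted p = 1.18e-16, adjusted p = 0.198 with an estimated correlation). Of the 83 ribosomal protein genes, 29 were higher and 2 lower, or 12 and 11 with library size only (36 and 3 adjusted over the list alone; median 0.73, 0.98 relative to all genes, camera adjusted p = 2.89e-06, adjusted p = 0.450 with an estimated correlation). Rpl38 rose by 2.68 ± 0.34 (adjusted p = 0.000219). Short transcripts were higher in ILC1/3P in general: the quartile of genes with the shortest transcripts had a median of 0.40 and the quartile with the longest -0.22. Random lists matched on length and level had a median of 1.04 beside the oxidative phosphorylation genes and 0.949 beside the ribosomal protein genes, so the ribosomal rise was no larger than that of transcripts of like length and level.

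Trafficking and activation genes moved in both directions. Ccr7 changed by -4.93 ± 0.82 (adjusted p = 0.00125), while Ccr2 rose by 5.79 ± 0.52 (adjusted p = 2.6e-05) and Itgal by 2.52 ± 0.45 (adjusted p = 0.00201). Of the egress genes, 3 were higher and 6 lower (3 and 7 adjusted over the list alone, camera adjusted p = 0.141). Of the residency genes, 5 were higher and 2 lower (8 and 2 adjusted over the list alone; median 1.25, 1.5 relative to all genes, camera adjusted p = 0.00586, adjusted p = 0.0855 with an estimated correlation). Rgs1 rose by 2.73 ± 0.34 (adjusted p = 0.000207) and Ccr9 changed by -3.12 ± 0.37 (adjusted p = 0.000161). Zbp1 (4.98 ± 0.87) and Gbp2 (4.56 ± 0.77) rose among 5 higher and 7 lower interferon genes (5 and 9 adjusted over the list alone, camera adjusted p = 0.793). H2-DMa (-3.75 ± 0.33) and H2-Ob (-7.13 ± 0.61) fell among 0 higher and 4 lower MHC class II genes (0 and 4 adjusted over the list alone, camera adjusted p = 0.0601). Hes1 changed by -2.87 ± 0.31 (adjusted p = 1e-04) among 0 higher and 2 lower Notch genes (0 and 2 adjusted over the list alone, camera adjusted p = 0.246). Not called as lists were the immediate early genes (5 and 6, 6 and 7 adjusted over the list alone, camera adjusted p = 0.657), the common gamma chain genes (3 and 2, 3 and 2 adjusted over the list alone, camera adjusted p = 0.619) and the glycolysis genes (2 and 2, 2 and 2 adjusted over the list alone, camera adjusted p = 0.793). With library size only the splits were 4 and 3 for residency, 2 and 9 for interferon, 3 and 8 for immediate early, 2 and 4 for common gamma chain and 0 and 6 for glycolysis genes. Nr4a1 changed by -2.95 ± 0.35, Nfkbia by 3.43 ± 0.32 and Il2rg by 2.58 ± 0.28.

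In all, 1592 genes were higher and 1571 lower in ILC1/3P than in CLP (23.5% of those tested). Among tested genes 7038 had no overlap between the groups' libraries, where chance gives 20%. This balance depended on scaling: with library size only, 946 were higher and 2807 lower, and the median of all genes moved from -0.25 to -0.93. With limma-trend on the deposited FPKM, which changes both the values and the test, the split was 1108 to 3183, and with length and GC trends removed it was 1867 to 1150.

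The comparison of ILC1/3P with ILCP asked how the CD94+ and PD-1+ gates differ. NK and ILC1 genes were higher in ILC1/3P, while Bcl11b, Rora, Gata3 and Themis were higher in ILCP. Ifng averaged 1288 ± 474 CPM in ILC1/3P (SD, n = 2) against 21.8 ± 8.35 CPM in ILCP (SD, n = 3), a log2 fold change of 5.88 ± 0.43 (SE, adjusted p = 0.000109). Klrb1c rose by 6.99 ± 0.54 (adjusted p = 5.19e-05), Klrk1 by 6.03 ± 0.53 (adjusted p = 0.000109), Ncr1 by 8.19 ± 0.90 (adjusted p = 0.000665) and Slamf7 by 7.24 ± 1.22 (adjusted p = 0.00271). Klrc1 rose by 6.98 ± 0.53 and its paralog Klrc2 by 7.40 ± 0.63 (adjusted p = 5.19e-05 and 0.000236). Klra5 was at least 743-fold and Xcl1 at least 703-fold higher than ILCP without counts, although Xcl1 varied widely between the ILC1/3P libraries (115 ± 132 CPM). Ube2l6 had 1 count in ILCP, a ratio of 705 (95% interval 126 to 27918). Of the NK and ILC1 genes, 21 were higher and 0 lower (22 and 0 adjusted over the list alone; median 2.92, 3.15 relative to all genes, camera adjusted p = 7.46e-26). It was the 1 list called between these groups with an estimated correlation (adjusted p = 0.00257).

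Single regulators and T lineage genes were lower in ILC1/3P than in ILCP, while their lists were not called. Bcl11b changed by -2.96 ± 0.52 (adjusted p = 0.00512), Rora by -1.85 ± 0.35 (adjusted p = 0.00497), Gata3 by -1.43 ± 0.30 (adjusted p = 0.00823) and Themis by -3.88 ± 0.51 (adjusted p = 0.0014). Tox changed by -2.02 ± 0.42 (adjusted p = 0.00802), a call lost without ILC1/3P replicate 2 (adjusted p = 0.0668). Of the regulators 1 was higher (Id2) and 4 lower (1 and 4 adjusted over the list alone, camera adjusted p = 0.0686), of the ILC2 genes 2 and 5 (3 and 7 adjusted over the list alone, camera adjusted p = 0.0686), of the T lineage genes 2 and 4 (2 and 4 adjusted over the list alone, camera adjusted p = 0.274) and of the ILC3 genes 2 and 3 (2 and 4 adjusted over the list alone, camera adjusted p = 0.491). With library size only the splits were 1 and 8 for the ILC2, 1 and 7 for the T lineage and 0 and 6 for the ILC3 genes, and the regulators, at 1 and 5, were called as a list (camera adjusted p = 0.0338). Tnfsf11 changed by -2.82 ± 0.45 (adjusted p = 0.00224). The Notch targets Hes1 (-3.05 ± 0.32, adjusted p = 0.000257) and Hey1 (-3.92 ± 0.78, adjusted p = 0.00627) were lower in ILC1/3P, in a list with 1 higher and 2 lower genes (1 and 2 adjusted over the list alone, camera adjusted p = 0.693). Of the multipotent genes 1 was higher and 7 lower (1 and 8 adjusted over the list alone; median -1.25, -1.02 relative to all genes, camera adjusted p = 0.0235, adjusted p = 0.231 with an estimated correlation). That list was not called without ILCP replicate 1 (adjusted p = 0.0949) or ILC1/3P replicate 1 (adjusted p = 0.102). Myb changed by -2.65 ± 0.49 (adjusted p = 0.0043) and Irf8 by 4.57 ± 0.79 (adjusted p = 0.00302). B-lineage genes had 0 higher and 2 lower, or 0 and 6 with library size only (0 and 2 adjusted over the list alone, camera adjusted p = 0.578). The largest losses by the naming rule were in Scamp4 (ENSMUSG00000078441, chromosome 10, 80602882 to 80615783, at least 359-fold lower, at the locus of Adat3), Gulp1 (at least 171-fold, not called without either ILC1/3P library, highest adjusted p = 0.0602), Adh1 (at least 137-fold), Kantr (at least 135-fold), Gdpd1 (at least 105-fold) and Scamp1 (at least 101-fold).

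Cell cycle, respiratory and ribosomal genes were higher in ILC1/3P than in ILCP as well. Cdk1 rose by 4.47 ± 0.31 (adjusted p = 3.69e-05), Birc5 by 3.08 ± 0.24 (adjusted p = 5.19e-05), Tyms by 3.02 ± 0.29 (adjusted p = 0.000174) and Pcna by 2.47 ± 0.26 (adjusted p = 0.00029). Of the cell cycle genes 13 were higher and 0 lower (14 and 0 adjusted over the list alone; median 1.29, 1.52 relative to all genes, camera adjusted p = 8.01e-14, adjusted p = 0.190 with an estimated correlation). Of the oxidative phosphorylation genes 51 were higher and 5 lower, or 30 and 11 with library size only (55 and 9 adjusted over the list alone; median 1.31, 1.54 relative to all genes, camera adjusted p = 1.11e-19, adjusted p = 0.231 with an estimated correlation). Of the ribosomal protein genes 41 were higher and 0 lower, or 14 and 2 with library size only (50 and 0 adjusted over the list alone; median 1.05, 1.28 relative to all genes, camera adjusted p = 8.37e-18, adjusted p = 0.231 with an estimated correlation). That median lay at the 96.7 percentile of random lists matched on length and level, and the oxidative phosphorylation median at the 99.99 percentile. With length and GC trends removed they lay at the 99.5 and 94.6 percentiles. Glycolysis genes were lower (0 higher and 4 lower, or 0 and 10 with library size only, 0 and 9 adjusted over the list alone; median -0.93, -0.695 relative to all genes, camera adjusted p = 0.0192, adjusted p = 0.354 with an estimated correlation and 0.0702 without ILCP replicate 1). Ldha changed by -1.35 ± 0.31 (adjusted p = 0.0125), a call lost without ILC1/3P replicate 2 (adjusted p = 0.103).

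The residency genes Cd69 and Rgs1 and the interferon response genes Rtp4 and Bst2 were higher in ILC1/3P than in ILCP. Cd69 rose by 3.07 ± 0.30 (adjusted p = 0.00019) and Rgs1 by 2.92 ± 0.34 (adjusted p = 0.000453), among 5 higher and 1 lower residency genes, or 3 and 2 with library size only (6 and 1 adjusted over the list alone; camera adjusted p = 0.0167, adjusted p = 0.192 with an estimated correlation), whose median was 0.46 but -0.15 with library size only, and 0.69 relative to all genes. Rtp4 rose by 3.24 ± 0.32 (adjusted p = 0.000204) and Bst2 by 4.12 ± 0.54 (adjusted p = 0.000843), among 5 higher and 0 lower interferon genes (5 and 0 adjusted over the list alone; camera adjusted p = 0.00194, adjusted p = 0.122 with an estimated correlation), whose median was 0.51 but 0 with library size only, and 0.74 relative to all genes. Ccr7 changed by -3.61 ± 0.77 (adjusted p = 0.00893, but 0.0513 without ILC1/3P replicate 1), among 0 higher and 5 lower egress genes (1 and 6 adjusted over the list alone, camera adjusted p = 0.0686), a list called with library size only (0 and 6, camera adjusted p = 0.0338). Not called as lists were the common gamma chain genes (0 and 4, 0 and 4 adjusted over the list alone, camera adjusted p = 0.431), the MHC class II genes (0 and 1, 0 and 3 with library size only, 0 and 1 adjusted over the list alone, camera adjusted p = 0.0686) and the immediate early genes (3 and 5, 0 and 6 with library size only, 3 and 5 adjusted over the list alone, camera adjusted p = 0.491). H2-Ob changed by -5.00 ± 0.57, Bcl2 by -2.18 ± 0.36 and Nr4a1 by -2.58 ± 0.35.

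**Figure D3:**
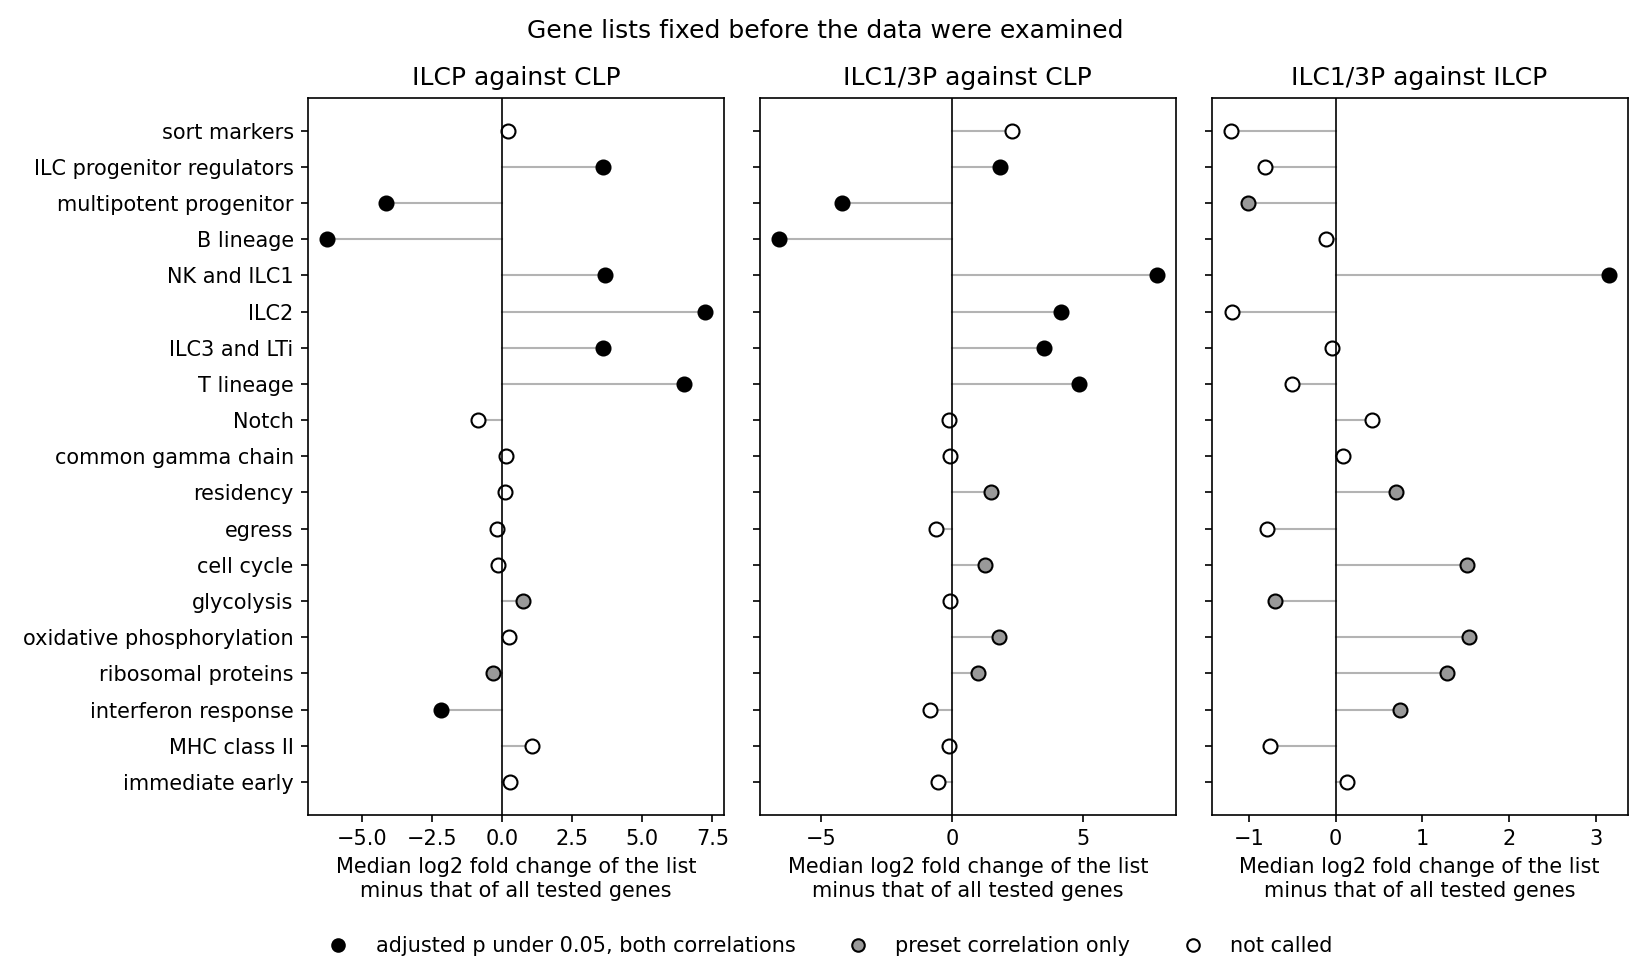
Median log2 fold change of each gene list minus the median of all tested genes (x axis), per comparison; black points were called by camera (adjusted p under 0.05) with both a preset and an estimated correlation, grey points with the preset correlation only, and white points were not called. The NK and ILC1 list of ILC1/3P against CLP lies furthest to the right at 7.80.

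In all, 1083 genes were higher and 1109 lower in ILC1/3P than in ILCP (16.3% of those tested), or 474 and 2141 with library size only, where the median of all genes moved from -0.23 to -0.86. Among tested genes 6020 had no overlap between the groups' libraries, where chance gives 20%. With limma-trend on the deposited FPKM the split was 662 to 2379, and with length and GC trends removed it was 1249 to 739. Without ILC1/3P replicate 2 the counts were 623 and 710, without ILCP replicate 1 they were 692 and 727, and without ILCP replicate 3 the lower count was 689.

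**Figure D4:**
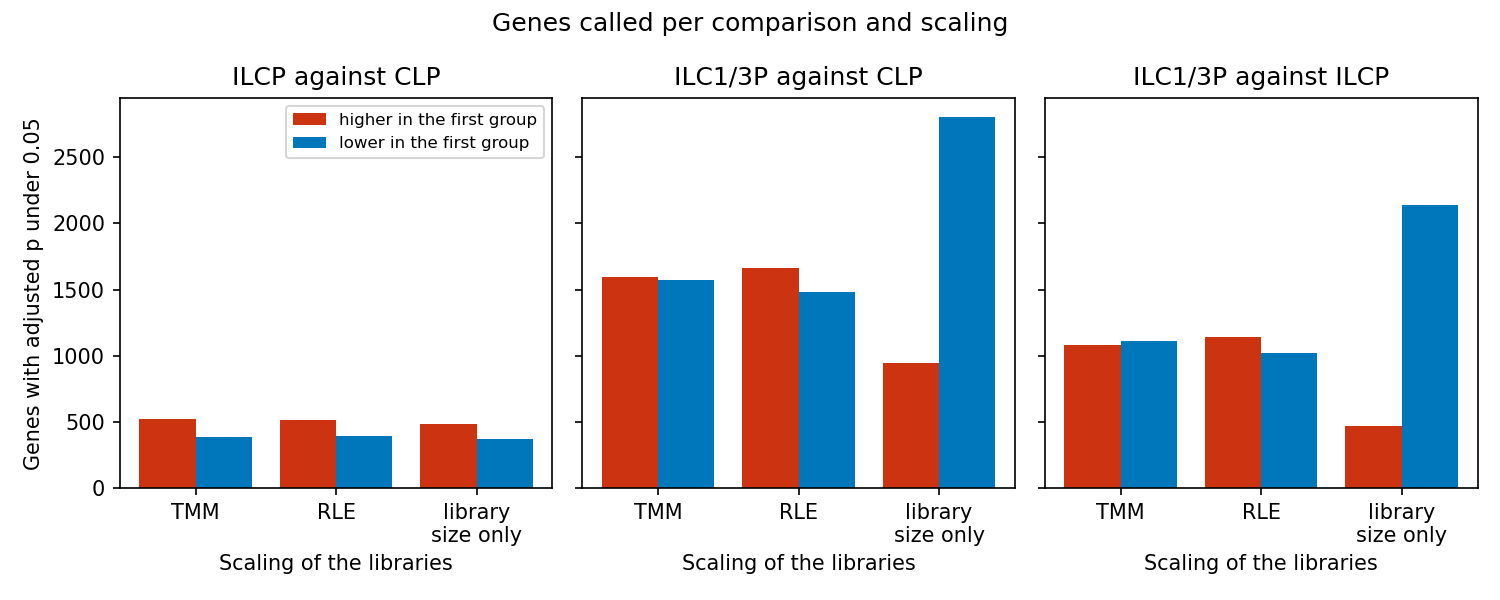
Number of genes called higher (red) and lower (blue) by edgeR at adjusted p under 0.05 (y axis) in each comparison, with TMM, RLE and library size as the scaling. The split between ILC1/3P and CLP changed from 1592 higher and 1571 lower with TMM to 946 and 2807 with library size only.

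Both innate lymphoid gates shared much of their difference from CLP. Of the genes called, 393 were higher and 278 lower in both, 11 were called in opposite directions, and independent lists of these sizes would share 62.3 and 45.1. Of the 393 shared higher genes, 83 were higher and 30 lower in ILC1/3P than in ILCP, and 280 were not called between them. Of the 278 shared lower genes, 47 were lower still in ILC1/3P than in ILCP, 16 were higher and 215 were not called. Fold changes across genes correlated at 0.615. In 20 simulations of unchanged groups the correlation averaged 0.426, with all 8 libraries drawn from the CLP means and the CLP group shared by both comparisons. Those simulated groups had at most 1 call in either direction, so they give no value to set beside the shared calls. The covariance was 4.58 against 0.680 in those simulations, a difference of 3.90. Both simulated comparisons also shared their CLP libraries, and the highest covariance of the 20 draws was 0.739. Genes without counts in CLP had none in the simulations and were left out there, while the observed values include them. The observed and simulated covariances and correlations thus cover different genes, and the simulated spread may differ from the real one. How far shared controls explain the excess therefore stays open. A split of the 3 CLP libraries would leave 1 library alone and was not made. The shared lower count fell to 156 without CLP replicate 2 and 161 without CLP replicate 3.

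Genes of other cell types were unevenly spread over the groups. Cpa3, a mast cell and basophil protease, averaged 536 ± 79.6 CPM in ILCP, 211 ± 36.6 CPM in ILC1/3P and 0.939 ± 1.63 CPM in CLP, while Hdc stayed at 2.17 ± 1.82 CPM in ILCP, and the list of 10 mast cell and basophil genes summed to 541 ± 80.4, 220.3 ± 43.8 and 3.70 ± 0.802 CPM in that order. The 25 myeloid genes summed to 794 ± 123.5 CPM in CLP, 28.4 ± 3.45 CPM in ILCP and 94.1 ± 9.34 CPM in ILC1/3P, led by Mpo in CLP and Lyz2 in ILC1/3P (39.9 ± 1.07 CPM). The 12 dendritic genes summed to 1725 ± 140.2 CPM in CLP, 192 ± 52.0 CPM in ILCP and 103 ± 17.6 CPM in ILC1/3P, led in CLP by Ly6d (853 ± 192 CPM), and Cox6a2 (353 ± 95.5 CPM in CLP) belongs to this list and to the oxidative phosphorylation list. The 10 megakaryocyte genes summed to 4.11 ± 3.25, 149.8 ± 19.4 and 75.8 ± 66.3 CPM in CLP, ILCP and ILC1/3P, with Itgb3 at 96.7 ± 12.7 CPM and Gp1bb at 51.1 ± 5.17 CPM in ILCP. Erythroid genes summed to 12.2 ± 3.84, 17.3 ± 3.28 and 24.7 ± 8.18 CPM, hepatocyte genes to 86.3 ± 9.002, 80.5 ± 34.7 and 46.4 ± 7.44 CPM, and endothelial and stromal genes to 80.1 ± 16.1, 117.2 ± 13.6 and 86.5 ± 38.4 CPM. Higher and lower calls against CLP were 0 and 3 in ILCP and 1 and 2 in ILC1/3P for myeloid genes, 1 and 6 in both for dendritic genes, 1 and 0 in both for mast cell and basophil genes, 2 and 0 in both for megakaryocyte genes, 1 and 0 in ILCP and 0 and 1 in ILC1/3P for hepatocyte genes, 1 and 0 in ILCP and 1 and 1 in ILC1/3P for endothelial and stromal genes, and 0 and 0 in both for erythroid genes. Between ILC1/3P and ILCP, edgeR called 1 myeloid gene higher, and 2 dendritic genes higher and 1 lower. Stab2 was at least 299-fold higher in ILCP and at least 376-fold in ILC1/3P than in CLP.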

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

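The tests on FPKM, on thinned counts and with length and GC trends removed were chosen only after the results were seen, and the other alternatives were planned. No gene called in a comparison was called in the opposite direction under any setting run. Of the 289 named pairs of gene and comparison, 238 were called, and 288 kept their side of the threshold with RLE size factors, 275 with library size only, 277 with the replicate block and 270 of 275 with a stricter filter. Library size only gave 946 higher and 2807 lower genes in ILC1/3P than in CLP, and 474 and 2141 in ILC1/3P than in ILCP. It leaves out the TMM factors, which were 0.671 and 0.753 in ILC1/3P and 1.05 to 1.23 in the other libraries. That lowers ILC1/3P fold changes over all genes: the medians moved from -0.25 to -0.93 against CLP and from -0.23 to -0.86 against ILCP. Why the factors differ was not tested. Library size only also called the regulators and egress lists of ILC1/3P against ILCP (camera adjusted p = 0.0338 each) and lost or turned no list call. DESeq2, with the false calls stated for it in the simulation, gave 869 higher and 741 lower genes in ILCP than in CLP. For that comparison voom gave 731 lower genes, no filter gave 602 lower genes and limma-trend on FPKM gave 740 lower genes, and for these the cause was not tested. Limma-trend on FPKM changes both the values and the test, and like library size only it applies no TMM factors. It also gave 3183 lower genes in ILC1/3P than in CLP, and 662 higher and 2379 lower than in ILCP. Removing length and GC trends gave 739 lower genes in ILC1/3P than in ILCP. For neither setting was the cause tested. With an estimated correlation camera called 7 lists for ILC1/3P against CLP and 1 against ILCP, in place of 11 and 8. The directional fry test called 14 lists between ILC1/3P and ILCP, and the mixed fry test, which asks only whether list members change at all, called 19, 19 and 19. Leaving out 1 library gave 347 to 613 higher and 215 to 502 lower genes in ILCP than in CLP, 1151 to 1639 and 1092 to 1584 in ILC1/3P than in CLP, and 623 to 1066 and 689 to 1233 in ILC1/3P than in ILCP. Shared genes ranged from 291 to 391 higher and 156 to 268 lower, and called lists from 10 to 11, 11 to 12 and 6 to 10. Lists that gained a call without some library were, beside oxidative phosphorylation, the common gamma chain genes of ILCP against CLP (adjusted p = 0.0407), the MHC class II genes of ILC1/3P against CLP (lowest adjusted p = 0.028), and the regulators, ILC2, egress and MHC class II genes of ILC1/3P against ILCP (lowest adjusted p = 0.0404, 0.0283, 0.0114 and 0.0195). Where 1 ILC1/3P library remained, it was assumed to vary like the other groups. Over all named pairs and left-out libraries, 2202 of 2308 kept their side of the threshold, 92 lost a call and 14 gained one. The replicate block gave 445 and 296, 1392 and 1232, and 944 and 809 higher and lower genes in the 3 comparisons, and the multipotent and residency lists of ILC1/3P against ILCP were not called (adjusted p = 0.0591 each), while the oxidative phosphorylation list of ILCP against CLP was (adjusted p = 0.00996). Of the named pairs 11 lost a call with the block and 1 gained one; those lost include Pdcd1 between ILC1/3P and ILCP, Il2ra of both groups against CLP, and Mcm2 and Mcm6 of ILCP against CLP. Libraries of ILCP and CLP with the same number had correlations of deviation of 0.0867, 0.0566 and -0.005. Pairs of these groups with unlike numbers ran from -0.093 to 0.0318, so replicates 1 and 2 correlated best with their own number and replicate 3 did not. The numbers are not said to mark a shared litter or day, so the block was kept as an alternative. Thinning every library to 1 total, which evens total counts but not the depth left over for less abundant genes, gave 551 and 402, 1625 and 1604, and 1085 and 1134 genes.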

Other observations

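The genes in this paragraph and the next were chosen after their values were seen, as were the tests of library depth, of transcript length for the gene lists and of other cell types. B2m averaged 12355 ± 5880.4 CPM in ILC1/3P (SD, n = 2) against 1260.1 ± 212 CPM in ILCP and 1204 ± 355 CPM in CLP (SD, n = 3 each), a log2 fold change of 3.29 ± 0.35 (SE) against ILCP (adjusted p = 0.000293) and 3.36 ± 0.35 against CLP (adjusted p = 7.77e-05). H2-K1 rose by 2.64 ± 0.23 (adjusted p = 0.000109), Psmb10 by 2.27 ± 0.28 (adjusted p = 0.000646), H2-D1 by 1.28 ± 0.23 (adjusted p = 0.00346) and Psmb8 by 0.81 ± 0.23 (adjusted p = 0.034) against ILCP. The median of all genes in this comparison moved from -0.23 to -0.86 with library size only. The size of these rises, above all that of Psmb8, therefore depends on the scaling. Random lists matched to the oxidative phosphorylation genes on transcript length and level had a median of 0.909 against ILCP. Whether these genes exceed transcripts of their own length and level was not tested. Car2 averaged 2725 ± 435 CPM in ILC1/3P and 98.6 ± 38.3 CPM in ILCP, and 99.1 ± 34.7 CPM in CLP. Lmo4 and Rxrg were highest in ILCP, at 732 ± 75.0 and 558 ± 116 CPM, against 99.5 ± 41.1 and 20.1 ± 14.0 CPM in ILC1/3P and 22.9 ± 7.67 and 0.981 ± 1.70 CPM in CLP. The imprinted neighbours H19 and Igf2 were highest there too, at 366 ± 172 and 65.5 ± 4.74 CPM, against 94.8 ± 48.1 and 8.78 ± 10.3 CPM in ILC1/3P (adjusted p = 0.0154 and 0.0495 against ILCP, 0.0251 and 0.00172 against CLP) and 33.1 ± 5.23 CPM and no counts in CLP. Il12a (788 ± 159.6 CPM) and the fetal progenitor gene Hmga2 (207 ± 44.0 CPM) were highest in CLP, against 2.14 ± 1.05 and 53.3 ± 32.1 CPM in ILCP and 3.07 ± 4.35 and 11.3 ± 1.08 CPM in ILC1/3P. The Y-linked gene Ddx3y averaged 35.5 ± 3.93 CPM in ILC1/3P, 116 ± 34.2 CPM in CLP and 130 ± 20.5 CPM in ILCP. Its edgeR adjusted p for ILC1/3P was 0.00377 against CLP and 0.00408 against ILCP. Whether the share of male cells differed between the groups was not tested, and other sex-linked genes are not reported here.

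Tcrg and Trb transcripts in ILCP and ILC1/3P came mostly from constant segments. The Tcrg constant genes summed to 5457 ± 1603 CPM in ILCP and 2396 ± 444 CPM in ILC1/3P, against 40.1 ± 57.9 CPM in CLP (SD), while the Tcrg variable genes summed to 136.0 ± 28.0, 66.5 ± 7.82 and 0.395 ± 0.685 CPM. The Trb constant genes summed to 3833 ± 482 CPM in ILCP, 5160.2 ± 665 CPM in ILC1/3P and 565 ± 193 CPM in CLP, while the Trb variable genes summed to 12.9 ± 6.25, 1.52 ± 1.81 and 2.67 ± 0.637 CPM. The Trb joining genes summed to 155 ± 21.4 CPM in ILCP, 102 ± 1.19 CPM in ILC1/3P and 5.72 ± 0.932 CPM in CLP. Trd variable genes summed to 22.5 ± 6.85 and 15.2 ± 7.56 CPM in ILCP and ILC1/3P, beside a constant gene at 74.6 ± 7.93 and 10.9 ± 12.1 CPM. The Trd constant gene thus led in ILCP but not in ILC1/3P. In CLP the Igh constant genes summed to 5707 ± 807 CPM and the Igh variable genes to 175 ± 56.1 CPM. Counting rules for receptor segments are not given in the sources used here, so reads over rearranged variable segments that were not counted remain open as a reason for the low Tcrg and Trb variable counts.

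ILC1/3P libraries had fewer detected genes than the other 6 libraries. Thinning to 1 total left a gap of 460 genes between the highest ILC1/3P library and the lowest other library (436 to 505 over 20 draws). Removing the 50 largest genes of each library before thinning left 385.5 (367 to 447), and thinning to 1 TMM-adjusted size, which also evens depth over the other genes, left 278.5 (246 to 302). Within the quartile of genes with the shortest transcripts the gap was 133.5 (113 to 152). These values argue against library depth, against a few genes taking most of the counts and against a loss of long transcripts as the whole cause. A smaller transcriptome in ILC1/3P is a candidate explanation that the remaining gap of 278.5 leaves open. So is less input RNA, since cell numbers were not analysed here.

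Oxidative phosphorylation and ribosomal protein genes were higher in ILC1/3P than in CLP, and both lists hold short transcripts (median length 1005 and 1094 bases, against 3072.5 for all tested genes). Neither list was called with an estimated correlation (adjusted p = 0.198 and 0.450), and with library size only 44 and 12 genes were higher and 13 and 11 lower. The oxidative phosphorylation median exceeded that of random lists matched on length and level by 0.511 (1.55 against 1.04, with a central range of 0.709 to 1.33), and after length and GC trends were removed it was 1.10, with 48 genes higher and 5 lower and the median of all genes at 0.06. Random lists then had a central range of 0.471 to 0.998, which argues against transcript length as the whole cause in the comparison with CLP. Against ILCP the same corrected median was 0.831, within the central range of its random lists (0.417 to 0.865). The comparison with ILCP therefore does not settle the question for this list. The ribosomal protein median differed from its random lists by -0.221 (0.73 against 0.949, with a range of 0.601 to 1.29), and with trends removed it was 0.513, with 21 genes higher and 4 lower and random lists at 0.656 (range 0.349 to 0.923). Part of that rise thus outlasted the correction, but transcripts of like length and level shared it. Transcript length and other causes therefore cannot be told apart for this list in the comparison with CLP. Against ILCP the ribosomal protein median was 1.05, within the central range of its random lists (0.431 to 1.07). With trends removed it was 0.831, above their range (0.299 to 0.763), with 35 genes higher and 0 lower. The comparison with ILCP thus gave no single answer for this list either. A biological difference between the sorted populations stays open and untested.

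Some genes best known from other cell types were abundant in the sorted populations, although lineage markers were gated out. Neutrophil precursors, mast cells or basophils, and T cells were weighed as sources of Mpo in CLP, Cpa3 in ILCP and Cd3g in ILCP and ILC1/3P. Beside Cpa3, the other 9 mast cell and basophil genes reached at most 1.072% of its level in an ILCP library. That argues against mast cells or basophils, since such cells would bring these transcripts too. Cd3d, Cd3e, Cd5, Cd6 and Trac together reached at most 6.718% of Cd3g, which argues against T cells rich in these 5 transcripts. Of the 23 T lineage genes tested, 16 in ILCP and 15 in ILC1/3P were higher than in CLP and 0 lower. Other cells of the T lineage therefore stay open as a source. Elane, Ctsg, Ms4a3 and Prtn3 reached 6.96% to 15.7% of Mpo in CLP libraries, mostly through Prtn3 (58.1 ± 7.97 CPM), so early neutrophil precursors and myeloid transcription within CLP themselves cannot be told apart, the bounds set being under 10% and at least 50%. A version of that test without Prtn3 stayed under the lower bound, and Prtn3 was added because it was itself lower in ILCP than in CLP (adjusted p = 0.034).

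For ILCP against CLP, fitted on those 6 libraries alone, the real split called 1134 genes and the highest of the other splits called 0. Only 1 of the 10 splits called as many genes as the real split, itself, and 10 splits are too few for a share under 0.05. Each other split put CLP and ILCP libraries on both sides, so any difference between the groups counted as spread within a side. Their 0 calls therefore say little about chance.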
